A study of Bos taurus with 8 samples.

How the data were processed

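RNA from bovine peripheral blood granulocytes was amplified, labelled with Cy3 and hybridised to single-colour Agilent arrays, 1 array per sample, per the labels' protocols. The source names give the same 4 cows in both groups: day 7 of the oestrous cycle before embryo transfer (4 arrays) and day 21 of pregnancy by embryo transfer (4 arrays). The replicate number is that of the cow. Samples of one group therefore come from separate animals. Each cow can serve as its own control, but the main fit, with no block, does not use this pairing. The order of sampling was the same in the 4 cows, so day, pregnancy, transfer and calendar time cannot be told apart within this design.

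The deposited scanner tables hold spot intensity from Agilent Feature Extraction 9.5, per the file headers and the submitters' processing notes. Per the file headers, the authors' processed signal is a background-subtracted, spatially detrended intensity with a surrogate value in place of signals not distinguishable from background; no normalization between arrays is recorded. Each array has 15744 spots, of which 536 are controls and 15208 are probes with 1 spot each. The deposited series table holds log2 values. Set against the scanner values, each of its columns is log2 of the processed signal minus 1 constant per array, within 0.00485, and that constant lies within 0.0162 of the array's 75th percentile. Its direction and scale are thus settled, and its column medians are between -3.53 and -3.29; why the constants differ slightly from the percentile stays unknown. It was used as an alternative.

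Normalised values were log2 of the processed signal minus the 75th percentile of the array. Control spots were left out, as were spots the scanner software marked as non-uniform or population outliers (between 0 and 12 per array, and 129 on the day 21 array of cow 2). Tested probes were well above background on at least 4 of the 8 arrays, whatever their group, which left 10459 and removed 4749. No spot was saturated. The lowest processed signal was 2.17 to 3.61 on 7 arrays and 10.6 on the day 7 array of cow 4, where the SD of the negative controls was 24.8 against 2.58 to 5.32 elsewhere. The 4 slides held both arrays of cow 1 with the day 7 array of cow 2 (slide 1), the day 21 array of cow 2 (slide 2), both arrays of cow 3 (slide 3) and both arrays of cow 4 (slide 4).

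Probes were named from the accession, gene identifier, gene name or description in the scanner tables through a RefSeq gene table of assembly ARS-UCD2.0, used for names only. A symbol was found for 7076 probes (2496 by accession, 1980 by gene identifier, 1586 by gene name and 1014 by description), and 8132 had none. A gene was represented by its probe with the highest mean over the 8 arrays, which gave 4998 genes; 229 genes had more than 1 probe, and GAPDH had 102. Where another tested probe of a named gene differed in sign or by much in size, its value is given. IFNGR1, BCL2, HSPA1A and EEF1A1 had other probes at -0.64, 0.85, -0.69 and 0.81. No coordinates are given, since the genome build of the array design is not given in the sources used here.

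Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, on the log2 scale, with no block, and p values were adjusted by the Benjamini-Hochberg method over all tested probes. A probe was called at an adjusted p under 0.05. Errors are standard errors of the log2 change unless SD is written. They and the p values of genes come from this unpaired fit unless another setting is named. With cow as a block the errors differ: 0.365 against 0.951 for OAS1X, and 0.935 against 0.793 for NUAK1. Of 23 gene lists, 20 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, on 4917 genes with no missing value, adjusted over the 20 lists. The eosinophil, basophil and mast cell, and platelet lists had fewer tested members and were not tested as lists. Camera with an estimated correlation and fry were run beside it.

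The named genes were fixed by a rule: CMPK2 and HES4; the 12 highest and 12 lowest changes among called genes that moved the same way in the 4 cows, filled up with the smallest p in each direction where fewer passed; the 4 members of smallest p in each tested list; and ACTB and GAPDH. Not every gene the rule names is given here. The interferon-stimulated list left out CMPK2 and HES4. Groups, designs, lists, the naming rule and the alternatives were fixed before the data were examined; any choice made later is described as such.

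The pairing was checked on deviations from the group means. Samples of the same cow correlated at 0.172 to 0.752, samples of different cows at -0.474 to 0.302, so the ranges overlap: the lowest pair of the same cow is that of cow 2, on separate slides, and the highest pair of different cows shares slide 1. The pairing therefore rests on the source names. In the fit with cow as a block, the smallest adjusted p was 0.105 and 0 probes were called, with 1031 higher and 938 lower at an unadjusted p under 0.05. Slide was tested as a fixed block, as a random block (consensus correlation 0.478) and within slides 1, 3 and 4. The day 21 array of cow 2 is alone on its slide, so it adds nothing to a change fitted with slide as a fixed block. Those values rest on the arrays of slides 1, 3 and 4 and hold no difference within cow 2.

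The fit was tested on simulated data: values for 10307 probes were drawn from their means and residual SDs, with 50 probes changed at each of 4 sizes. Of 50 probes changed by 1 on the log2 scale, 3 were called; of 50 changed by 2, 28; of 50 changed by 3, 40; and of 50 changed by 4, 44, with 6 false calls among the unchanged probes. With noise at the residual SD of the fit with cow as a block, 11, 32, 41 and 48 of 50 were called, with 5 false calls. These values were also fitted without a block, and no difference between cows was simulated. The counts are therefore not those of the fit with cow as a block. A shift of 1 given to the 25 interferon-stimulated genes among 4919 simulated independent genes was found by camera (adjusted p = 4e-13, and 0.0039 with an estimated correlation), and 0 of the other lists were called. In the real data the estimated correlation of this list was 0.244. The simulation therefore does not show how camera behaves with genes that move together. The alternatives covered the block, the slide, median and quantile normalization, normexp background correction (offset 50), the filter on dim probes, the deposited log2 table, an intensity trend, array weights, each array and each cow left out, the threshold, the set test and the probe per gene.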

Results

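Granulocytes, the blood leukocyte fraction made up mainly of neutrophils, were profiled in 4 cows sampled before and after embryo transfer. Each cow gave a sample on day 7 of the oestrous cycle, before transfer and not pregnant, and a sample on day 21 of pregnancy after transfer. The 8 samples were hybridised to 8 single-colour bovine oligonucleotide arrays, 4 per group. The median processed signal of an array was between 49.1 and 186.9 intensity units, and between 56.8% and 74.9% of the 15208 probes were well above background. The number of arrays, 4 per group, limits the precision; the median standard error of a log2 change was 0.456. Over 10459 tested probes, arrays of the same group correlated at 0.875 to 0.969 and arrays of different groups at 0.854 to 0.970, while arrays on the same slide correlated at 0.942 to 0.970. Pairs on the same slide include both samples of cows 1, 3 and 4, so slide and cow largely coincide here. The first principal component, 40.1% of the variance, separated the 3 arrays of slide 1 (both of cow 1 and day 7 of cow 2), at -84.8, -68.1 and -43.3, from the other 5, at 21.1 to 52.1.

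The comparison asked how transcripts in circulating granulocytes differ between the period when the embryo secretes interferon tau and the cycle before transfer. The gene with the smallest p among those higher on day 21 was OAS2, a 2'-5'-oligoadenylate synthetase that senses viral double-stranded RNA, at -3.72 ± 0.37 on day 7 and -0.79 ± 1.03 on day 21 (normalised log2 signal, SD, n = 4). Its log2 change of 2.93 ± 0.51 (SE), 7.60-fold, was positive in 4 of 4 cows. On the other side stood CDKN2B, an inhibitor of cyclin-dependent kinases 4 and 6 and a member of a family that halts cells in G1, with a log2 change of -3.26 ± 0.52 that was negative in 4 of 4 cows. ADAM19, a membrane-anchored metalloprotease, gave -3.21 ± 0.52. None of these genes passed the test over all probes.

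With limma, 0 probes were higher and 0 were lower at an adjusted p under 0.05. The smallest adjusted p was 0.219. At an unadjusted p under 0.05, 522 probes were higher and 461 lower, in all 983 or 9.40% of those tested. By chance 523 would be expected if the arrays were independent. Of 10307 probes measured in both samples of each cow, 3065 (29.7%) differed in the same direction in the 4 cows, against 12.5% expected for independent signs. Probes share the same arrays, so their signs can move together, and this share was not tested against chance. Without the day 21 array of cow 1, limma called 12 probes higher and 29 lower, and without both arrays of that cow 15 and 21. Genes named here that passed without that array were OAS2 (adjusted p = 0.0204), ISG15 (0.0252), CXCL5 (0.0352), RAB7B and CCL2 (0.0436 each) and FBXW2 (0.0483), higher, and ADAM19 (0.0252), DYNLRB2 (0.0294) and CDKN2B (0.0352), lower. Without that cow they were NUAK1 (0.0133), OAS2 (0.0361), ISG15 (0.0441) and OAS1X (0.0453), higher, and DYNLRB2 (0.0441) and ADAM19 (0.0453), lower. Leaving out any other single array or cow gave 0 calls in both directions. At an unadjusted p under 0.05, limma gave 199 higher and 220 lower without cow 2, and 181 and 187 without cow 4. Both totals are under 523, but that number holds for independent arrays, and the samples of a cow are not independent. Other splits of the arrays that part the samples of each cow gave from 27 to 931 such probes. These totals therefore do not show that an excess is absent. With array quality weights limma called 879 higher and 821 lower, among them 24 genes named here on each side. These calls lean on cow 4, whose day 7 and day 21 arrays had weights of 3.27 and 7.02, against 0.293 and 0.295 for cow 1. The day 7 array of cow 4 also had the highest SD of negative controls, 24.8. With slide as a random block limma called 2 higher and 10 lower. The 4 with a gene symbol were CDKN2B (adjusted p = 0.0318), ADAM19 (0.0318), NHERF4 (0.0348) and P2RY12 (0.0474), all lower.

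The other genes with the smallest p on the higher side are given as values. NUAK1, an AMPK-related kinase, had a log2 change of 4.07 ± 0.79, with 0.32 in cow 1 and 4.32 to 6.38 in the other cows; it was well above background on 2 of the 4 arrays of day 7. RAB7B, a small GTPase of late endosomes and lysosomes, gave 2.89 ± 0.62, and CCL2, the monocyte-attracting chemokine, 2.75 ± 0.63, also well above background on 2 of the 4 arrays of day 7. AVPI1 gave 2.39 ± 0.49, and CHAF1A, the large subunit of chromatin assembly factor 1, 2.30 ± 0.49. Changes between 1.53 and 2.01 were found for EGFL7 (2.01), FBXW2 (1.98), TMCC3 (1.96), MLXIPL (1.90), NAV3 (1.55) and URGCP (1.53). MLXIPL was well above background on 1 of the 4 arrays of day 7, with a surrogate for signal near background on 2, and a dimmer probe of NAV3 gave 0.14. These 12 genes, OAS2 included, were higher in 4 of 4 cows, with limma adjusted p values of 0.274 to 0.310. They were chosen by small p on the same arrays, so the agreement of the cows is no separate evidence.

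On the lower side, TTC36 had a log2 change of -2.93 ± 0.57 and NHERF4, a PDZ-domain scaffold protein, -2.89 ± 0.67. NHERF4 was well above background on 1 of the 4 arrays of day 21. Each had a surrogate for signal near background on 1 array of day 21, TTC36 in cow 2 and NHERF4 in cow 1, so these changes depend on that level. P2RY12, the ADP receptor known from platelets, gave -2.45 ± 0.45. MTMR11 gave -2.30 ± 0.51, and DYNLRB2, a dynein light chain, -2.16 ± 0.40. Changes between -1.60 and -1.85 were found for FAM216A (-1.85), CYRIA (-1.77), RARG (-1.76), IMPACT (-1.68) and FGD6 (-1.60), of which RARG is a retinoic acid receptor and IMPACT an inhibitor of the GCN2 stress kinase. These 12 genes, CDKN2B and ADAM19 included, were lower in 4 of 4 cows, with limma adjusted p values of 0.219 to 0.314. Their choice by small p likewise favours such agreement.

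Interferon-stimulated genes moved upward as a list. Of 25 tested members 18 were higher on day 21 and 7 lower, and the median log2 change was 0.74 (1.67-fold), with a positive median in 4 of 4 cows. The list passed limma's camera test with a preset correlation (adjusted p = 0.0111) and did not pass when the correlation between genes was estimated (adjusted p = 0.535 with an estimated correlation). No member passed over all probes, and 1 member, OAS2, passed when adjusted over the list alone (adjusted p = 0.00393). ISG15, a ubiquitin-like modifier and one of the most strongly interferon-induced transcripts, had a log2 change of 2.92 ± 0.93, OAS1X, another oligoadenylate synthetase, 2.78 ± 0.95, and RTP4, a chaperone of G protein-coupled receptors, 1.14 ± 0.38. ISG15 was 4.16 higher in cow 3, 3.97 in cow 4 and 2.51 in cow 2, but 1.04 in cow 1. Not every member followed: IFIT3, named after its values were seen, gave -2.15 ± 0.90 and was lower in 4 of 4 cows. MX2 (1.86 ± 0.70) and OAS1Z (2.09 ± 0.79), also chosen after their values were seen, were higher in 4 of 4 cows; OAS1Z was well above background on 1 of the 4 arrays of day 7.

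The shift of the interferon-stimulated genes was 0.77 with slide as a fixed block (camera adjusted p = 0.0207). The day 21 array of cow 2, alone on its slide, adds nothing to that value. The median within slide 3 was 1.14 and within slide 4 it was 1.15. Within slide 1, where the day 21 array of cow 1 is set against the day 7 arrays of cows 1 and 2, it was -0.17, while cow 1 alone gave 0.66. Without the day 7 array of cow 1 the list had a median of 0.63 and did not pass (adjusted p = 0.108).

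**Figure D1:**
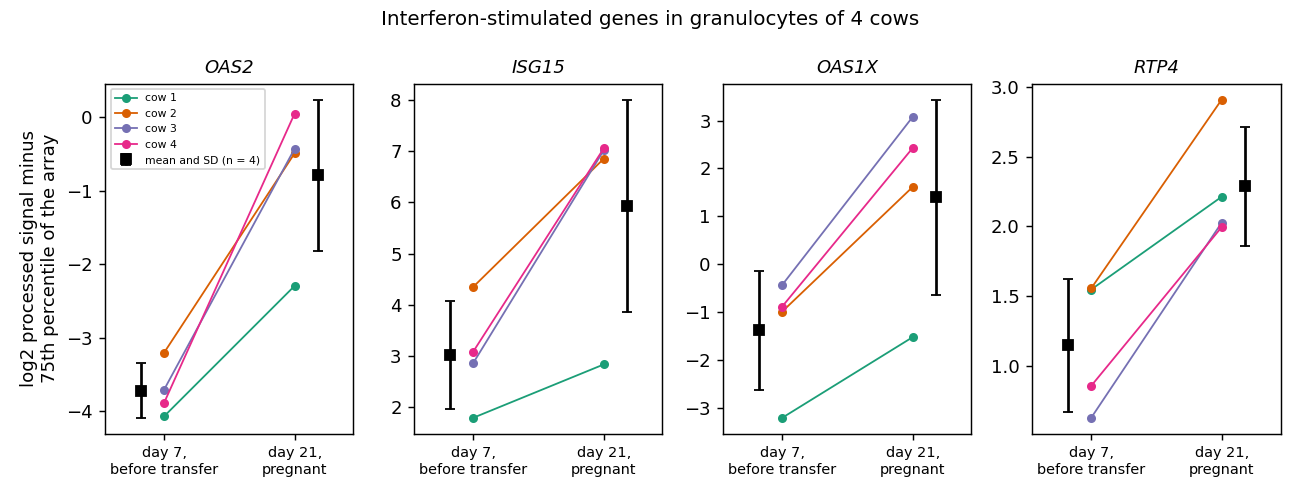
Normalised log2 signal (vertical axis, log2 processed signal minus the array's 75th percentile) of 4 interferon-stimulated genes in each cow on day 7 and day 21; lines join the samples of a cow, and squares with bars show the group mean and SD (n = 4). Each gene was higher on day 21 in 4 of 4 cows, and for ISG15 the day 21 sample of cow 1, at 2.83, lay below those of the other cows, at 6.85 to 7.05.

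Receptors and signalling components of the interferon pathways fell as a list, with 15 of 20 members lower and a median log2 change of -0.58 (camera adjusted p = 0.0128; adjusted p = 0.329 with an estimated correlation). The within-cow medians were 0.00, -1.01, -0.23 and -0.35 in cows 1 to 4, and -0.64 within slide 1. With slide as a fixed block the median was -0.44 (adjusted p = 0.00644), and after normexp background correction it was -0.24 (0.0320, 75th percentile) or -0.32 (0.0336, quantile). No member passed over all probes or when adjusted over the list alone. IFNGR1, a chain of the interferon gamma receptor, gave -0.97 ± 0.49, TLR3, an endosomal RNA sensor, -1.03 ± 0.62, SOCS3, a feedback inhibitor of JAK signalling, -0.87 ± 0.53, and MAVS, the mitochondrial adaptor of RNA sensing, -0.70 ± 0.36. Without the day 21 array of cow 1 (median -0.48, adjusted p = 0.0613) or the day 7 array of cow 2 (-0.31, 0.148) the list did not pass.

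The cell cycle list rose, with 13 of 13 members higher on day 21 and a median log2 change of 0.87 or 1.83-fold (camera adjusted p = 0.000457; adjusted p = 0.329 with an estimated correlation). Its median was positive in 4 of 4 cows, from 0.46 in cow 1 to 1.44 in cow 4, and 0.73 with slide as a fixed block (adjusted p = 5.49e-05). Within slides 1, 3 and 4 it was 0.82, 0.59 and 1.44. CDK1, the kinase that drives entry into mitosis, had a log2 change of 2.44 ± 0.86 (a surrogate for signal near background on the day 7 array of cow 1), and its partners CCNB1 and CCNB2 gave 1.07 ± 0.33 and 0.78 ± 0.35. BIRC5, a member of the chromosomal passenger complex, gave 0.99 ± 0.42. No member passed over all probes or when adjusted over the list alone.

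Transcripts of neutrophil granules and antimicrobial proteins fell as a list, with 13 of 17 members lower and a median log2 change of -0.38 (camera adjusted p = 0.0127; adjusted p = 0.501 with an estimated correlation). PGLYRP1, a peptidoglycan-binding granule protein, had a log2 change of -1.44 ± 0.35, lower in 4 of 4 cows, and was the 1 member to pass when adjusted over the list alone (adjusted p = 0.0350). The cathelicidins CATHL1, CATHL4 and CATHL5, precursors of antimicrobial peptides, gave -1.85 ± 1.00, -1.89 ± 1.04 and -1.08 ± 0.48. Cow 1 set much of this: CATHL1 differed by -5.56 and CATHL4 by -5.21 in that cow, and by -0.10 to -1.26 in the other cows. On the day 21 array of cow 1 both are surrogates for signal near background, at -8.70, as is CATHL5 in cow 2, so these differences depend on that level. The list median was -1.53 in cow 1, against -0.01, 0.06 and -0.10 in cows 2 to 4. Without the day 21 array of cow 1 it was -0.16 and the list did not pass (adjusted p = 0.585), nor did it without both arrays of that cow (-0.32, 0.436). With slide as a fixed block it was -0.65 (adjusted p = 5.49e-05), and within slide 1 it was -1.82.

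Mature neutrophil markers also fell, with 13 of 15 members lower and a median log2 change of -0.32 (camera adjusted p = 0.0393; adjusted p = 0.329 with an estimated correlation). FCGR2B, the inhibitory receptor for IgG, gave -1.32 ± 0.45, and NCF1, a subunit of the NADPH oxidase, -1.26 ± 0.52, each lower in 4 of 4 cows. LTB4R, the leukotriene B4 receptor, went the other way at 0.79 ± 0.35. The list medians were -0.53 and -0.68 in cows 1 and 2 and 0.02 and 0.03 in cows 3 and 4. The median was -0.24 with slide as a fixed block (adjusted p = 0.0218) and -0.50 within slide 1. The list did not pass without the day 21 array of cow 1 (median -0.27, adjusted p = 0.446), the day 7 array of cow 1 (-0.28, 0.0522) or cow 2 (-0.21, 0.148), or both arrays of cow 1 (-0.18, 0.436) or cow 2 (-0.23, 0.122). No member passed over all probes or when adjusted over the list alone.

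Markers of other blood cells moved beside these groups. Monocyte and macrophage markers rose as a list, with 8 of 9 members higher and a median log2 change of 0.63 (camera adjusted p = 0.0417; adjusted p = 0.329 with an estimated correlation; 0.0543 with cow as a block). CD14, the lipopolysaccharide co-receptor, had a log2 change of 1.60 ± 0.45 and was the 1 member to pass when adjusted over the list alone (adjusted p = 0.0465). It differed by 0.04 in cow 1 and by 1.37 to 2.70 in the other cows. VCAN gave 0.86 ± 0.34, MRC1 0.96 ± 0.48 and C1QC 0.75 ± 0.72; a dimmer probe of VCAN gave -0.06. The list median was 0.85 with slide as a fixed block (adjusted p = 0.0106) and 0.77 within slide 1, and was positive in 4 of 4 cows. The list did not pass without the day 21 array of cow 1 (median 0.53, adjusted p = 0.123) or cow 3 (0.41, 0.172), the day 7 array of cow 2 (0.37, 0.148) or cow 4 (0.44, 0.0775), or both arrays of cow 1 (0.50, 0.136), cow 3 (0.65, 0.0869) or cow 4 (0.50, 0.0988).

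T cell markers had a median log2 change of -0.63, with 7 of 9 members lower and a negative median in 4 of 4 cows. The list did not pass (camera adjusted p = 0.0596; after normexp background correction the median was -0.25 or -0.34, adjusted p = 0.140 or 0.164; without the day 7 array of cow 1 -0.45, 0.290) but passed with cow as a block (adjusted p = 0.0439, and 0.363 with an estimated correlation). It also passed without the day 21 array of cow 2 (median -0.53, adjusted p = 0.0458), the day 7 array of cow 3 (-0.59, 0.0422) or cow 4 (-0.45, 0.0463), or both arrays of cow 2 (-0.53, 0.0308). CD2 gave -1.14 ± 0.51, CD3G -0.75 ± 0.48 and CD8A -0.63 ± 0.41, while CD5 gave 0.77 ± 0.49. The NK and cytotoxic cell list (7 of 8 members higher, median 0.29, adjusted p = 0.886) did not pass. NCR1, well above background on 2 of the 4 arrays of day 21, gave -1.41 ± 0.91, KLRD1 0.57 ± 0.55, NKG7 0.45 ± 0.61 and KLRB1 0.30 ± 0.38. The B and plasma cell list (5 of 7, 0.15, 0.886) did not pass either, with MS4A1 at 0.68 ± 0.48, CD79A at 0.52 ± 0.32, JCHAIN at 0.22 ± 0.62 and BLK at -0.52 ± 0.37. Nor did the erythroid list (2 of 3, 0.23, 0.765), with ALAS2 at 0.53 ± 0.42, AHSP at 0.23 ± 0.35 and EPB42, well above background on 1 of the 4 arrays of day 7, at -0.08 ± 0.48. In these lists no member passed over all probes or when adjusted over the list alone.

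**Figure D2:**
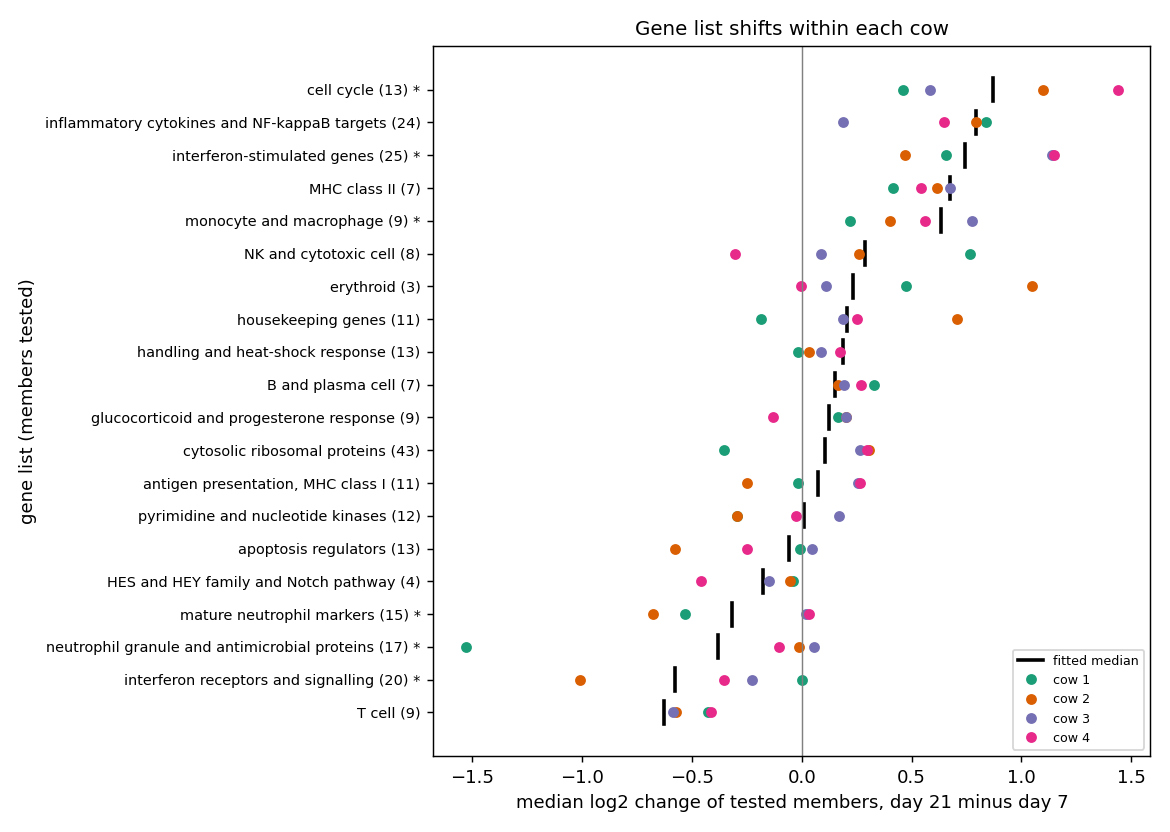
Median log2 change, day 21 minus day 7 (horizontal axis), of the tested members of 20 gene lists (vertical axis, number of members in brackets); each dot is the median within 1 cow, the black bar is the median of the fitted changes, and a star marks a camera adjusted p under 0.05 with the preset correlation. The cell cycle and interferon-stimulated lists lie above 0 in 4 of 4 cows, as do the MHC class II, inflammatory, monocyte and B cell lists. The T cell and Notch lists lie below 0 in 4 of 4 cows. The granule list is at -1.53 in cow 1 and between -0.10 and 0.06 in the other cows.

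Inflammatory cytokines and NF-kappaB targets had a median log2 change of 0.79, with 18 of 24 members higher and a positive median in 4 of 4 cows. The list did not pass (camera adjusted p = 0.138; median 0.39 and adjusted p = 0.322 with slide as a fixed block, 0.45 and 0.814 without the day 7 array of cow 1) but passed with cow as a block (adjusted p = 0.0423, and 0.363 with an estimated correlation). It also passed without the day 21 array of cow 3 (median 1.29, adjusted p = 0.0139), the day 7 array of cow 4 (0.95, 0.0259) or both arrays of cow 3 (0.84, 0.0109). CCL2 was the 1 member to pass when adjusted over the list alone (adjusted p = 0.0309). The neutrophil-attracting chemokines CXCL5 and CXCL2 gave 3.05 ± 0.98 and 1.67 ± 0.65, and CCL3 gave 1.26 ± 0.60, each higher in 4 of 4 cows. MHC class II genes were all positive, 7 of 7, with a median of 0.68 (adjusted p = 0.150; median 0.21 and adjusted p = 0.258 with no filter on dim probes; 0.0439 with cow as a block, 0.0112 with slide as a fixed block and 0.363 with cow as a block and an estimated correlation). BOLA-DQA2 gave 0.85 ± 0.51, BOLA-DRB3 0.77 ± 0.85, BOLA-DYB 0.76 ± 0.46 and BOLA-DMA 0.68 ± 0.34.

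Genes of apoptosis did not move together (6 of 13 higher, median -0.06, adjusted p = 0.765). XIAP, an inhibitor of caspases, had a log2 change of -1.40 ± 0.35, lower in 4 of 4 cows, and was the 1 member to pass when adjusted over the list alone (adjusted p = 0.0282); a dimmer probe gave -0.40. BCL2, an antiapoptotic protein, gave 0.78 ± 0.34, CYCS, cytochrome c, 0.65 ± 0.39, and CASP1, the inflammasome caspase, -0.52 ± 0.33. MHC class I presentation (6 of 11 higher, median 0.07, adjusted p = 0.886) did not pass, with JSP.1 at 1.09 ± 0.50, PSME2 at 0.41 ± 0.38, PDIA3 at 0.36 ± 0.31 and PSMB8 at -0.60 ± 0.49. The glucocorticoid and progesterone response (7 of 9, 0.12, 0.886) did not pass, with PAQR7, a membrane progesterone receptor, at -1.06 ± 0.43, ANXA1 at 0.48 ± 0.76, NR3C1 at 0.47 ± 0.63 and PGRMC1 at 0.26 ± 0.37; a dimmer probe of NR3C1 gave -0.39. The handling and heat-shock response (8 of 13, 0.19, 0.886) did not pass, with FOS at -0.90 ± 0.35, HSPA1A at -0.86 ± 0.36, IER3 at 0.79 ± 0.40 and HSP90AB1 at 0.77 ± 0.33.

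No probe was assigned to CMPK2 or HES4, the genes the series names, by the annotation used here, so these genes are not analysed here. Their relatives were measured. The pyrimidine and nucleotide kinases showed no common shift (6 of 12 higher, median 0.01, adjusted p = 0.537). Within that list DCK, deoxycytidine kinase, had a log2 change of -1.41 ± 0.45 and was lower in 4 of 4 cows, and DHODH gave -0.98 ± 0.44, AK3 -0.90 ± 0.46 and UMPS 0.53 ± 0.34. The mean of that list was -0.20, of the other sign than its median. In the HES and HEY family and Notch pathway (1 of 4 higher, median -0.18, mean 0.07, adjusted p = 0.894), HES6 gave 1.64 ± 0.78, HES1 -1.01 ± 1.20, NOTCH2 -0.26 ± 0.39 and NOTCH3 -0.09 ± 0.58. HES6 was well above background on 1 of the 4 arrays of day 7 and 3 of day 21.

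Cytosolic ribosomal proteins (29 of 43 higher, median 0.11, adjusted p = 0.759) and housekeeping genes (8 of 11, 0.21, 0.765) did not pass. The ribosomal list passed without the day 7 array of cow 3 (median 0.26, adjusted p = 0.0371), and its median was -0.13 without the day 21 array of that cow (0.235). With all arrays and an estimated correlation, which was 0.376 for this list, the camera adjusted p was 0.897. RPLP0 gave 1.41 ± 0.57, RPS27 0.79 ± 0.46, RPL7 0.67 ± 0.36 and RPL4 0.64 ± 0.39, while a dimmer probe of RPLP0 gave -0.02. Among housekeeping genes EEF1A1 gave 0.68 ± 0.91, HPRT1 0.68 ± 0.34, YWHAZ 0.54 ± 0.50 and TUBB -0.56 ± 0.57. ACTB differed by -0.17 ± 0.42, and by 0.22 without cow 1. GAPDH differed by 0.18 ± 0.38 at its brightest probe, and by -0.0012 after quantile normalization; the 102 probes of this gene had a median of 0.18, from -0.67 to 1.60. In the lists of inflammation, MHC, apoptosis, hormone and handling responses, kinases, Notch, ribosomal and housekeeping genes, CCL2 and XIAP were the members to pass when adjusted over the list alone, and none passed over all probes.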

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

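The tests of slide, probe brightness, monocyte RNA, immature granulocytes, neutrophil share and the day 21 array of cow 1 were chosen only after the results were seen; those on other splits of the arrays were set down before.

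Among 256 groups of 4 values, 13 held an array far from the other 3 (a gap to the nearest other value that is most of the range), and chance alone gives about 1 in 20. Of these, 3 lie in the day 21 array of cow 1 and 3 in the day 7 array of that cow. On day 21, ISG15 in cow 1 was at 2.83 (others 6.85 to 7.05), ANXA1 at 3.20 (5.62 to 5.94) and GAPDH at 4.41 (5.63 to 5.65). On day 7, RPS27 in cow 1 was at 3.15 (others 1.37 to 1.54), UMPS at -0.22 (0.53 to 0.62) and CD79A at 1.96 (1.55 to 1.61). In cow 2, SOCS3 on day 7 was at -2.05 (others -3.98 to -3.66), CATHL5 on day 21 at -7.69 (-6.05 to -5.75), a surrogate for signal near background, and the median of the HES, HEY and Notch genes on day 21 at -3.24 (-2.34 to -2.16). The median of the nucleotide kinases on day 21 was -0.092 in cow 3 (others 0.30 to 0.32). The day 21 array of cow 2 had 129 outlier spots (others 2 to 12). The day 7 array of cow 4 had a lowest processed signal of 10.6 (others 2.56 to 3.61) and a negative-control SD of 24.8 (3.08 to 5.32).

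The counts were set against the 35 splits of the 8 arrays into 4 and 4. The count of called probes was 0 in the real split and at most 87 in another; a count of 0 is reached by 35 of 35 splits whatever the data, so this says nothing about chance. The count at an unadjusted p under 0.05 was 983, against at most 2078, and 6 of 35 splits reached it, so chance was not excluded. The 5 others all put the 3 arrays of slide 1 together, a structure of the samples that follows the slide and cow 1; with slide as a fixed block limma still called 0 probes. The split of cows 1 and 2 from cows 3 and 4 gave the 87 calls. Among the 8 splits that part the samples of each cow, the real one gave the highest count, 983 against 931, but 8 are too few for a share under 0.05. The number of lists past camera was 6, and 2 of 35 splits gave as many, with 6 the highest elsewhere, so chance was not excluded there either. Among the 8 splits that part the samples of each cow, the highest elsewhere was 4, and 8 are again too few to decide.

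By list, chance was not excluded for the interferon-stimulated genes, where 9 of 35 splits gave a camera p as small as 0.00111 (smallest elsewhere 1.38e-10, in the split of both arrays of cow 1 and the day 7 arrays of cows 3 and 4 from the rest). Nor was it for the interferon receptors and signalling (4 of 35; 0.00256 against 0.00119), the granule genes (13 of 35; 0.0019 against 2.38e-05), the mature neutrophil markers (5 of 35; 0.00982 against 5e-04) and the monocyte markers (4 of 35; 0.0125 against 0.000282). For the cell cycle list, 1 of 35 splits, the real one, gave a camera p of 2.28e-05, with 3.98e-05 the smallest elsewhere, but 27 of the 35 splits put both days of some cows in 1 group, so this count does not decide for samples paired by cow. This list also did not pass with an estimated correlation (adjusted p = 0.329) or directional fry (0.13). The same limit holds for the counts of the other lists. Of the 35 splits, 8 part the 2 samples of each cow, too few for a share under 0.05 whatever the data. The smallest camera p among the 7 others of these was 5.17e-07 for the interferon-stimulated genes, 0.00353 for their receptors and 2.38e-05 for the granule genes. It was 5e-04 for the mature neutrophil markers, 0.000287 for the cell cycle and 0.0261 for the monocyte markers. Among these 8 the real split gave the smallest p for the receptors, the cell cycle and the monocyte markers, but not for the other lists.

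The upward shift of the interferon-stimulated genes was set against 3 technical explanations. A difference between slides as the whole cause is argued against by the 3 cows with both arrays on 1 slide, whose lowest within-cow median was 0.66 (SD over the 4 cows 0.344). The brightness of the probes is argued against as well: the median lay at percentile 100 of 10000 random lists matched on mean level, which had a 95% range of -0.20 to 0.33. RNA from monocytes, whose CD14 was at 0.64 on day 7 and 2.24 on day 21, stays open: the list median exceeded the monocyte median by 0.364 in the mean of the cows (SD over cows 0.218), but 8 of the 9 monocyte markers were well above background on each day 7 array, and such a baseline hides a small rise in monocytes. Pregnancy, the day after oestrus and the transfer itself are biological differences the design joins, and remain untested against each other.

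For the cell cycle genes, a difference between slides as the whole cause is argued against by a lowest within-slide cow median of 0.462, just above the SD over cows of 0.455; this margin is thin, and the bound was set after the values were seen. Their median lay at percentile 99.98 of matched random lists (100 when rounded), which argues against the brightness of the probes. Immature granulocytes, which divide and transcribe granule proteins, may contribute; the granule list, which should rise with them, had a mean of -0.397 over cows with an SD of 0.758, so the test leaves this open. A biological difference between the days, in the same cells, was not tested.

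Granule genes and mature neutrophil markers were both lower, both in cow 1 and the mature markers also in cow 2: the medians of cows 1 to 4 were -1.53, -0.01, 0.06 and -0.10 for the granule list, and -0.53, -0.68, 0.02 and 0.03 for the mature markers. For the granule list much of the fall goes with the day 21 array of cow 1, but the part of this array is not fully settled. Without it the mean went from -0.587 to -0.0164 and the median from -0.383 (SD over cows 0.758) to -0.162. The camera adjusted p went from 0.0127 to 0.585. Without both arrays of cow 1 the median was -0.319 (0.436). A difference between slides is argued against for this list, as the 2 arrays of cow 1 share slide 1. Its median was -0.647 with slide as a fixed block (camera adjusted p = 5.49e-05). For the mature markers neither is settled: without that array the median was -0.274 against -0.316 (SD over cows 0.37) while the mean went from -0.431 to -0.221 and the call ended (0.446), and with slide as a fixed block the median was -0.24 (0.0218), smaller than without the block. A lower share of neutrophils that raised all other cell types alike is argued against by the T cell list alone. The monocyte and T cell medians moved apart by 0.989 (SD over cows 0.293), with the T cell median below 0 in 4 of 4 cows. In cow 1 the NK, erythroid, B cell and monocyte medians were 0.765, 0.473, 0.329 and 0.222, against -0.425 for T cells. The comparison of monocytes with T cells cannot decide on a lower share of neutrophils beside more cells of only some other types. That share and a higher content of monocytes stay open, and no biological difference between the days was tested.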

How the results depend on the processing

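The tests that join cow as a replicate block with an estimated correlation or with fry were chosen only after the results were seen; the other alternatives were planned. There were 36 settings for 128 results. Of the values under alternatives, 523 for lists and 2584 for named genes kept their direction and, where a test was run, their side of the threshold. No named gene was called in the main fit, so for genes this side is that of no call. Among list values, 60 lost a pass, 15 gained one and 40 reversed.

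The counts of called probes, 0 higher and 0 lower with limma (522 and 461 at an unadjusted p under 0.05), stayed 0 with cow as a replicate block, with slide as a fixed block, in the normalization, filter, series table and trend alternatives, at an adjusted p under 0.10 and with a 1.5-fold bound. They were 2 and 10 with slide as a random block and 879 and 821 with array weights, which ran from 0.293 and 0.295 for the arrays of cow 1 to 3.27 and 7.02 for those of cow 4. Leaving out arrays or cows gave 0 to 15 higher and 0 to 29 lower: 12 and 29 without the day 21 array of cow 1, 15 and 21 without both arrays of that cow. At an unadjusted p, the counts were 1031 and 938 with the replicate block, 806 and 704 with the random slide block, 1889 and 1593 with weights, and 181 to 985 and 187 to 860 with arrays left out. The cause was not tested.

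The number of lists past the threshold, 6, was 2 with weights, 2 with probes above background on all arrays (fewer genes tested), 0 with an estimated correlation, 0 with directional and 2 with mixed fry, and 2 to 8 with arrays left out. The estimated correlation and fry keep the medians and allow for genes that move together. With an estimated correlation the adjusted p was 0.535 for the interferon-stimulated genes (median 0.74), 0.329 for the interferon receptors (-0.58), 0.501 for the granule genes (-0.38), and 0.329 for each of the mature neutrophil (-0.32), cell cycle (0.87) and monocyte (0.63) lists. With directional fry these were 0.34, 0.34, 0.435, 0.211, 0.13 and 0.211. With mixed fry, which asks for changes in either direction, the interferon-stimulated (0.0788), receptor (0.637), granule (0.418), mature neutrophil (0.169) and monocyte (0.275) lists did not pass, while apoptosis did (median -0.056, 0.000898). With the replicate block joined to an estimated correlation or to directional fry, 0 lists passed; the interferon-stimulated list had an adjusted p of 0.37 and 0.0866, and the cell cycle list 0.363 and 0.0645. The cell cycle list passed in the other settings that have a test.

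The interferon-stimulated median was 0.63 to 1.09 with arrays left out, did not pass without the day 7 array of cow 1 (adjusted p = 0.108), and was -0.17, 1.14 and 1.15 within slides 1, 3 and 4. With weights the receptor (-0.51, 0.0605), granule (-0.28, 0.291), mature neutrophil (-0.074, 0.559) and monocyte (0.75, 0.0598) lists did not pass. With probes above background on all arrays the same 4 lists gave -0.62 (0.0593), -0.091 (0.681), -0.31 (0.0656) and 0.62 (0.0593). With no filter the receptor (-0.58, 0.0766), granule (-0.38, 0.0547) and mature neutrophil (-0.31, 0.179) lists did not pass, and the inflammatory list did (0.78, 0.039). The granule list did not pass with normexp and the 75th percentile (-0.22, 0.0837), nor the monocyte list with the mean of a gene's probes (0.50, 0.0892) or the replicate block (0.63, 0.0543). MHC class II passed with the replicate block (0.68, 0.0439), the fixed (0.62, 0.0112) and the random slide block (0.51, 0.0461), and the inflammatory (0.79, 0.0423) and T cell (-0.63, 0.0439) lists with the replicate block. With arrays left out, lists that did not pass in the main fit did so in 4 settings for T cells (adjusted p of 0.0308 to 0.0463), in 3 for inflammation (0.0109 to 0.0259) and in 1 for ribosomal proteins (0.0371). With arrays left out the medians ran from -0.61 to -0.28 (receptors), -0.70 to -0.16 (granule), -0.49 to -0.18 (mature neutrophil), -0.73 to -0.36 (T cells) and 0.27 to 1.29 (inflammatory). Apart from the number of genes tested, the cause was not tested.

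Within slides, with no test, the list medians below moved by more than the SD over cows, except those of the granule list in slide 3 and the mature neutrophil markers in slides 3 and 4, which moved by less and changed sign. Slides 3 and 4 hold 1 cow each. Slide 1 gave -1.82 for the granule genes, 0.13 for inflammation, -0.36 for apoptosis, 0.0094 for handling, -0.25 for ribosomal proteins, 0.21 for Notch, 1.23 for NK cells, -0.15 for T cells and 0.49 for B cells. Slide 3 gave 0.057 for the granule genes, 0.019 for mature neutrophil markers, 0.19 for inflammation and 0.087 for handling. Slide 4 gave 0.032 for mature neutrophil markers, 1.44 for the cell cycle, 0.54 for MHC class II, -0.13 for the hormone response, -0.46 for Notch, -0.30 for NK cells, -0.41 for T cells and 0.27 for B cells.

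Among lists, 40 values reversed. Pyrimidine and nucleotide kinases gave -0.0013 with median scaling, -0.0056 with normexp and quantile normalization, -0.042 with no filter, -0.0070 with the series table, -0.014 with weights, and -0.15 to 0.10 with arrays left out. MHC class I gave -0.020 with quantile normalization, -0.018 with normexp before it, -0.061 with no filter, -0.063 with the series table, and -0.11 to 0.18 with arrays left out. Apoptosis gave 0.019 with normexp and the 75th percentile, and -0.19 to 0.13 with arrays left out. With weights, NK cells gave -0.018, B cells -0.034 and the erythroid list -0.0060. With arrays left out, the ranges were -0.054 to 0.60 (NK), -0.12 to 0.29 (B cells), -0.13 to 0.29 (ribosomal), -0.019 to 0.32 (handling), -0.035 to 0.50 (housekeeping) and -0.35 to 0.025 (Notch). The cause was not tested.

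Among named genes, 67 values passed the threshold in an alternative, 34 higher and 33 lower: 48 with weights, 9 without the day 21 array of cow 1, 6 without both arrays of that cow and 4 with the random slide block. OAS2 and ISG15 passed with weights (3.65, adjusted p = 0.00161; 3.76, 0.00314), without that array (3.43, 0.0204; 3.95, 0.0252) and without that cow (3.31, 0.0361; 3.55, 0.0441). Another 37 values reversed, none of them called. With slide as a fixed block ANXA1 gave -0.059, NOTCH3 0.20, JCHAIN -0.069, EPB42 0.38 and GAPDH -0.0057; with a random slide block NOTCH3 gave 0.10 and EPB42 0.16. EPB42 gave 0.22 with quantile normalization, 0.055 with normexp before it and 0.18 with normexp and the 75th percentile. GAPDH gave -0.0012 with quantile normalization, with or without normexp, and AHSP -0.038 and -0.021 with normexp and quantile or 75th percentile normalization. With weights PGRMC1 gave -0.16, KLRD1 -5.14e-05, KLRB1 -0.055, JCHAIN -0.045, ALAS2 -0.16 and ACTB 0.15. With arrays left out the ranges were -0.40 to 0.22 (ACTB), -0.039 to 0.42 (AHSP), -0.071 to 1.13 (ANXA1), -0.41 to 0.26 (EPB42), -0.22 to 0.63 (JCHAIN), -0.090 to 0.86 (KLRD1), -0.029 to 0.82 (NKG7), -0.61 to 0.35 (NOTCH3) and -0.057 to 0.90 (NR3C1). The cause was not tested.

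Signal over background limits the reach: 4749 probes that were not well above background on at least 4 arrays were left out, and 56.8% to 74.9% of probes per array were well above it.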

Other observations

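No test was run for this part, and its genes were chosen after their values were seen. HDC, the histamine-forming enzyme of basophils and mast cells, had a log2 change of 1.07 ± 0.47, and the eosinophil markers CCR3 and ALOX15 gave -0.63 ± 0.91 and -1.02 ± 0.76; IL4 gave -0.29. These lists had too few tested members for a test. The platelet integrin chains ITGA2B and ITGB3 gave 0.10 ± 0.52 and 0.72 ± 0.55, while P2RY12, the ADP receptor also found on platelets, gave -2.45 ± 0.45.

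Within the interferon-stimulated list the genes of the oligoadenylate synthetase family did not all point one way. The synthetases OAS2, OAS1X and OAS1Z had log2 changes of 2.93, 2.78 and 2.09. OASL, the synthetase-like member, gave -1.28 ± 0.61 and was lower in 4 of 4 cows. IFIT3 gave -2.15 ± 0.90, also lower in 4 of 4 cows, while MX1 (0.93 ± 0.43) was higher in 4 of 4 and EIF2AK2 (1.43 ± 0.63) in 3 of 4. OAS1Z was well above background on 1 array of day 7 and 3 of day 21. None passed over all probes.

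Cow 1 had the lowest levels of the interferon-stimulated list on both days. Its list median was -0.64 on day 7 and -0.28 on day 21, where the other cows had 0.97, 0.21 and -0.03 on day 7 and 1.32, 1.21 and 0.97 on day 21. The cause was not tested.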
